A study of Mus musculus with 3 samples.

How the data were processed

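Single-cell RNA was measured in 3 libraries of circle of Willis arteries from wild-type C57BL/6 mice aged 8 weeks, 1 each from sham animals, animals that formed aneurysms and animals with ruptured aneurysms. The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and cell barcode from 10x Genomics v3 droplet libraries sequenced on a NextSeq 2000. The mm10 build, Cell Ranger 4.0 and Seurat 4.02 are named without further detail, per the submitters' processing notes. The barcodes had been filtered before deposit, with at least 500 UMIs in each. Cell labels were not used here. All values below were computed from these counts with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and leidenalg 0.10.2, with edgeR 4.0.16 in R 4.3.3 for 1 alternative scaling, and drawn with matplotlib 3.10.9.

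Cells were kept with at least 200 genes, at least 500 UMIs and at most 15% mitochondrial UMIs. Of 7560, 8958 and 9001 barcodes in the sham, formed and ruptured libraries, 2737, 3261 and 4703 had fewer than 200 genes, mostly red blood cells, and 200, 267 and 142 more were over the mitochondrial limit. Doublets were scored per library with Scrublet as called from scanpy. Its automatic threshold called 2, 96 and 4 cells, too few to be usable, so the highest-scoring cells were removed at 0.8% per 1000 cells, which took out 171, 236 and 138 cells. The kept cells hold 23240707, 40140252 and 20536428 UMIs. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (seed 0) gave 27 clusters. No batch integration was run, since group and library are the same.

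Clusters were named from 28 marker sets by likeness only. For each set the level of its markers was taken relative to the highest cluster, and a name needed at least 3 markers detected in 25% of cells and a mean score of at least 0.3. Clusters with a mean haemoglobin share of at least 5% were kept apart. A cluster with at least 6 macrophage, monocyte or microglia markers and no leading set was called mononuclear phagocyte. Shares of classes were taken among all kept cells, among immune classes and among vessel wall classes, with exact binomial 95% intervals.

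Within a class the UMIs of all cells of a library were summed and expressed as CPM (UMI counts relative to all UMIs of the class in that library). The ratio of CPM between libraries has an exact 95% interval, binomial given the total of both counts. Where a library had no count, a bound was taken at a floor of 3 counts over the class. For log2 ratios 0.5 was added to each count. A class needed 100 cells in both libraries, and a single cluster 20. Of 38 gene lists, a list was used in a class with at least 5 members that had a summed count of at least 20, and its median log2 ratio was placed among 10000 random lists of the same size matched on expression in 20 bins, with the middle 95% given as the random range. This range describes these libraries and is no test. The 3 comparisons were formed against sham, ruptured against sham and ruptured against formed. No p-value was computed, as 1 library per group gives no spread between animals.

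Genes were named by rule. In each comparison and in 5 classes (smooth muscle, fibroblast, endothelial and the 2 immune classes with the most cells in their smallest library) the 3 genes higher and the 3 lower with the largest ratio at the interval bound nearest 1 were taken. They needed a CPM and a count of at least 50 in the higher library and at least 20% of the CPM of its highest class. Mitochondrial, ribosomal, haemoglobin and immunoglobulin genes and unnamed gene models were left out. Up to 4 members with the highest CPM of each described list were added, and sex-linked genes. Of the genes picked by this rule, Rasl11a and Rsad2 lead a cluster of their class and Areg, named in macrophages, leads a mononuclear phagocyte cluster. The results do not describe these 3, except for values of Areg under other processing. Gene coordinates come from GENCODE vM21 on GRCm38. Mx1 and Clec7a were listed but are absent from the deposited genes.

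The ratio and list methods were tested on simulated data built from smooth muscle, formed against sham, with 12391 genes. Genes made 2-fold and 4-fold higher gave median log2 ratios of 1.00 and 1.99. The intervals held the true ratio for 95.7% of unchanged and 91% of changed genes. These shares check the intervals against simulated counting error only. They do not cover counts that are uneven between cells, so they do not show that precision is high for smooth muscle. The spread between animals is unknown. Of 100 unchanged lists 5 lay outside the random range. Those lists were drawn at random from genes simulated independently, so a share of this size was set in advance. It does not show how often real lists, whose genes may vary together, leave the range. Scaling by TMM lowers every log2 ratio by 0.15 in smooth muscle for formed against sham and by 0.10 for ruptured against sham. It lowers those of T cells by 0.14 for formed against sham. It raises those of macrophages, by a log2 factor ratio of -0.14 for ruptured against sham and -0.10 for ruptured against formed.

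The filters, markers, gene lists, comparisons, naming rule for genes and 17 alternatives were fixed before the data were examined. The doublet score threshold, the scoring rule and thresholds for cluster names, the mononuclear phagocyte class, the choice of which gene lists to describe, the endothelial comparisons with the ruptured library (91 cells) and 7 more alternatives were chosen after the data were seen. Those fixed beforehand were other mitochondrial limits (5% and 25%), at least 500 genes, no doublets removed, resolutions 0.5 and 2.0, each library clustered on its own, other scalings, equal weight per cell, cells thinned to 1000 UMIs, other list summaries and other count minimums. Spliced and unspliced reads, sequence variants and copy number were not examined, because only gene counts were deposited.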

Results

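Cells of the circle of Willis, the ring of arteries at the base of the brain, were profiled by droplet single-cell RNA sequencing in 3 libraries from wild-type C57BL/6 mice aged 8 weeks. There was 1 library from sham animals, 1 from animals that formed cerebral aneurysms (the formed library) and 1 from animals whose aneurysms had ruptured (the ruptured library). How aneurysms were induced and how many animals each library holds were not given in the sources used here. The sham, formed and ruptured libraries held 7560, 8958 and 9001 cell barcodes with 34907914, 52910080 and 34186160 unique molecular identifiers (UMIs, each a counted transcript molecule) over 32285 genes. Barcodes with more than 50% haemoglobin UMIs, as red blood cells give, made up 33.9%, 35.5% and 50.4% of these. After filtering, 4452, 5194 and 4018 cells remained, with medians of 4921, 6455 and 4039.5 UMIs and of 1774, 2079.5 and 1267 genes per cell. With 1 library per group no difference has a replicate check and none was tested, so the intervals given are exact 95% intervals that cover counting error only.

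The first question was how the cell makeup of the arterial ring differed between the libraries. The cells fell into 27 clusters, which were named by their likeness to marker genes (smooth muscle-like, fibroblast-like and so on, shortened here to the class name). Smooth muscle cells, the contractile cells of the artery wall, made up 61.7% of the sham cells, 42.7% of the formed cells and 12.9% of the ruptured cells. Their share in the formed library was 0.692 times that in the sham library (95% interval 0.654 to 0.732), and in the ruptured library 0.210 times (0.191 to 0.230). Immune cells together made up 22.4%, 34.2% and 74.6%. Neutrophils, the short-lived granulocytes of the blood, numbered 17 of 4452 sham cells, 54 of 5194 formed cells and 1188 of 4018 ruptured cells. Their shares of 0.382%, 1.04% and 29.6% stood 2.72 times higher in the formed library than in the sham library (1.55 to 5.01) and 77.4 times higher in the ruptured library (48.2 to 133). Cells named monocytes made up 1.01%, 2.85% and 15.1%, which is 14.97 times higher in the ruptured than in the sham library (11.1 to 20.7). Their cluster had 3 monocyte markers among its 10 leading genes, which also included Arg1, Apoc2, Gpnmb and Fabp5, genes of lipid-laden macrophages.

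The formed library stood apart in other classes. Fibroblasts, the matrix-producing cells of the outer wall and the meninges, made up 3.80% of the sham cells, 11.6% of the formed cells and 2.76% of the ruptured cells, 3.06 times higher in the formed than in the sham library (2.57 to 3.65). A class that carried macrophage, microglia and monocyte markers together, called mononuclear phagocytes here, made up 4.78%, 21.1% and 14.5%. Resident-type macrophages with the mannose receptor gene Mrc1 among their leading genes made up 6.87%, 3.60% and 3.91%. The 4 phagocyte classes together made up 14.3%, 29.4% and 35.5%, so that the formed library stood 2.06 times above the sham library (1.88 to 2.26) and the ruptured library 1.21 times above the formed library (1.12 to 1.30). B cells made up 2.52%, 0.270% and 2.22%, T cells 2.81%, 2.14% and 3.98%, mast cells 1.48%, 0.289% and 0.498%, and dendritic cells 0.921%, 1.12% and 2.84%. Pericytes, the mural cells of small vessels, numbered 71, 22 and 2. Endothelial cells, which line the vessel, made up 3.62%, 4.83% and 2.26%.

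Because shares of all cells add up to a fixed total, they were also taken within the vessel wall classes and within the immune classes. Among wall cells, smooth muscle made up 87.3%, 71.7% and 71.8%, fibroblasts 5.37%, 19.5% and 15.3%, and endothelial cells 5.11%, 8.11% and 12.6% in the sham, formed and ruptured libraries. Among immune cells, neutrophils made up 1.71%, 3.04% and 39.7%, and macrophages 30.7%, 10.5% and 5.24%. Clusters led by haemoglobin genes, kept out of these classes by a threshold set after the data were seen, held 6.38%, 5.60% and 5.70% of the cells. The filters bear on several shares: neutrophils of the ruptured library had a median of 482 genes per cell, and smooth muscle cells of the 3 libraries had median mitochondrial shares of 8.00%, 8.50% and 7.91%. A mitochondrial limit of 5% took out most smooth muscle cells and turned the direction of 3 log2 share ratios, to -0.37 for all phagocytes (ruptured against formed), -0.15 for endothelial cells (formed against sham) and -0.94 for T cells (ruptured against sham).

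**Figure D1:**
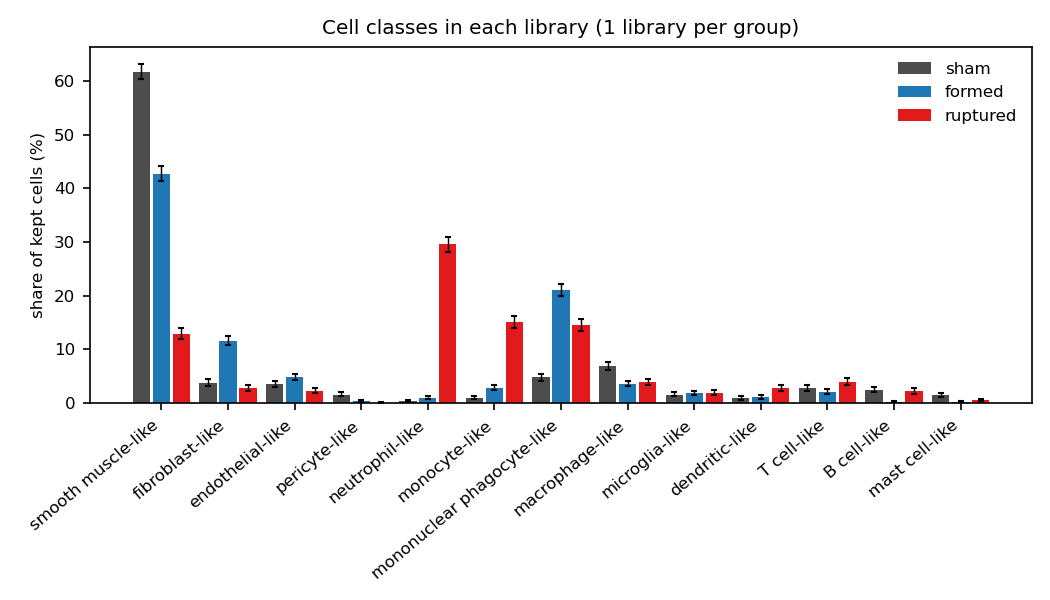
Share of the kept cells (percent, linear axis) in each marker-named class in the sham (grey), formed (blue) and ruptured (red) libraries, with exact binomial 95% intervals as error bars. Smooth muscle-like cells make up 61.7%, 42.7% and 12.9%, and neutrophil-like cells 0.382%, 1.04% and 29.6%.

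The second question was how gene expression within a class differed between the formed and sham libraries. Smooth muscle cells of the formed library held more transcripts of the extracellular matrix. All 20 measured genes of the fibrillar and elastic matrix list were higher, 19 of them at least 2-fold, and their median log2 ratio was 1.76, where the middle 95% of random gene lists matched on expression ran from -0.19 to 0.39. Bgn, which encodes biglycan, a small proteoglycan of collagen fibrils, stood at 1163 CPM (UMI counts relative to all UMIs of the class) in the sham and 4457 CPM in the formed library, 3.83-fold higher (3.77 to 3.90). Eln, elastin, the rubber-like protein of arterial laminae, stood at 475 and 1624.5 CPM, 3.42-fold higher (3.33 to 3.51), and Col1a2, a chain of type I collagen, was 3.10-fold higher (2.95 to 3.25). The list of smooth muscle modulation, genes gained by smooth muscle cells that leave the contractile state, had a median of 2.68 with 12 of 16 genes at least 2-fold higher. Its members Mgp, an inhibitor of vessel calcification, and Fn1, fibronectin, were 4.25-fold (4.18 to 4.32) and 7.39-fold (7.15 to 7.65) higher. The contractile list did not stand apart, with a median of -0.06 and none of 18 genes 2-fold higher or lower. Acta2, smooth muscle actin, was 0.992 times the sham level (0.988 to 0.997), and the 8 contractile genes that were not used to name the class had a median of 0.31 within a random range of -0.49 to 0.42.

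Lists often lay outside the random range in this comparison: of 34 lists in smooth muscle 22 lay above and 3 below, of 35 in fibroblasts 16 and 4, and of 32 in endothelial cells 16 and 5. In the same smooth muscle cells the basement membrane list had a median of 0.54 (Sparc, a collagen-binding protein, 3.54-fold higher) and the unfolded protein response list one of 0.61 (Calr, a chaperone of the endoplasmic reticulum, 2.29-fold higher). TGF-beta response genes had a median of 1.01, with 9 of 16 at least 2-fold higher, among them Pmepa1, a feedback inhibitor of the pathway, at 2.37-fold (2.30 to 2.43), and with Id3, a transcription regulator, 2.31-fold lower (2.28 to 2.34). Matrix proteases and protease inhibitors were both higher, with medians of 1.04 and 0.998. Ctsd, a lysosomal protease, was 3.03-fold higher (2.87 to 3.20) and Adamts1, a proteoglycan-cleaving protease, was 1.99-fold lower (1.93 to 2.05). Of 9 measured renin angiotensin and vasoactive genes, 7 were lower, with a median of -0.73. Gucy1a1 and Gucy1b1, the subunits of the nitric oxide receptor guanylate cyclase, were 2.37-fold (2.22 to 2.54) and 2.03-fold (1.89 to 2.18) lower. Interferon response and MHC class I genes had medians of 0.65 and 0.75, the first of which lay within the random range when cells were thinned to 1000 UMIs (0.31) and the second with the mean of members in place of the median (0.40). NF-kB response genes had a median of 0.77, with Nfkbia, an inhibitor of NF-kB, 3.75-fold higher (3.62 to 3.87). Proliferation genes had a median of 1.97, which lay inside the random range after thinning (0.53). Of the genes near human intracranial aneurysm loci 7 were measured, with a median of 0.36 inside the random range of -0.36 to 0.73.

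By a rule of size over all genes, those that stood highest in formed smooth muscle were Smoc2, a matricellular calcium-binding protein (2.27 CPM in sham, 85.0 CPM in formed, 37.5-fold, 26.6 to 54.6), Dbp, a transcription factor of the circadian clock output (4.06 and 101 CPM, 24.9-fold, 19.2 to 32.8), and Gask1b (24.6-fold, 18.0 to 34.4). Those that stood lowest included Cebpd, a transcription factor of the acute phase response, 4.76-fold lower, and Cenpl, a centromere protein gene, 4.74-fold lower. Different clusters held most smooth muscle cells of the 2 libraries: clusters 2 and 4, led by Pln and Myh11, held 38.9% and 34.8% of the sham cells, and clusters 11 and 17, led by Cnn1 and Acta2, held 29.7% and 33.0% of the formed cells. Within a single cluster the matrix median ran from 0.27 to 0.79 and the modulation median from 0.15 to 0.83, so that the difference of the class was larger than that in any of its 6 clusters, of which 11 and 17 held only 48 and 32 sham cells. The matrix median lay inside the random range in clusters 4, 5 and 17, and the modulation median in clusters 5 and 6. Immediate early genes, which also mark stress of dissociation, were lower in formed smooth muscle (median -0.49), with Fos 3.91-fold lower (3.82 to 3.998), but higher in cluster 17 alone (0.44). Chemokine genes were higher (median 2.04, and 0.93 with the automatic doublet threshold), at a summed level of 487 CPM against 67699.5 to 112580 CPM in the monocytes and mononuclear phagocytes of that library.

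**Figure D2:**
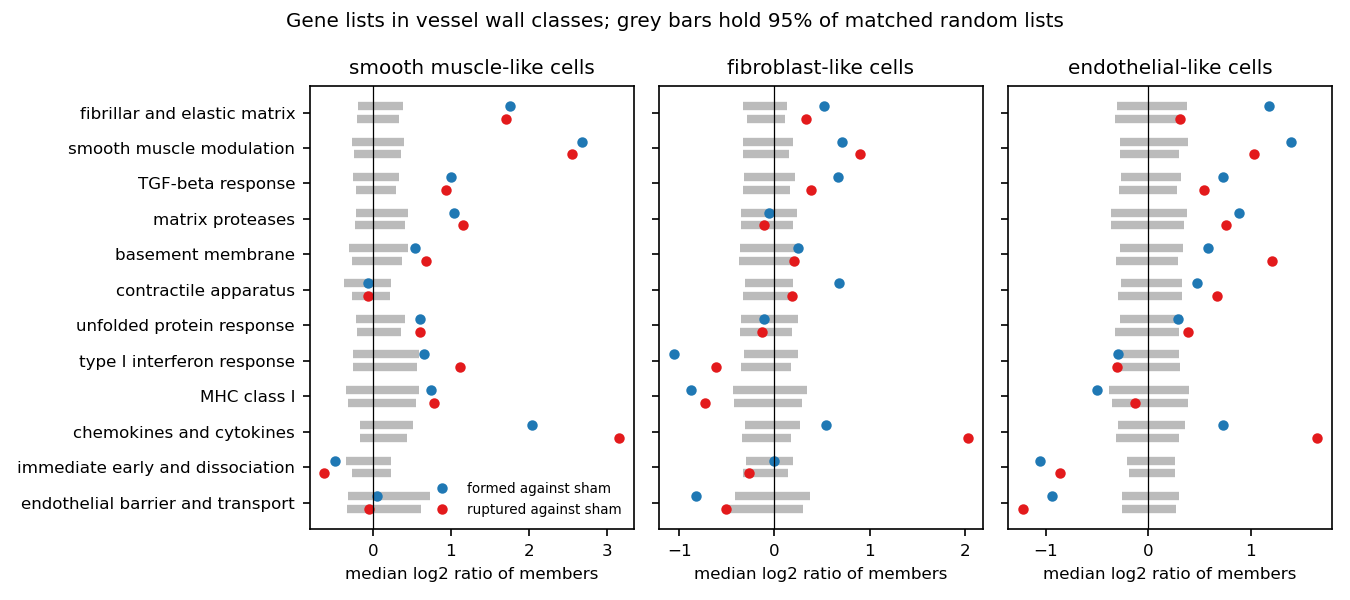
Median log2 ratio of each gene list in smooth muscle-like, fibroblast-like and endothelial-like cells, formed against sham (blue) and ruptured against sham (red), with grey bars for the middle 95% of 10000 random lists matched on expression. The fibrillar and elastic matrix list lies at 1.76 and 1.70 in smooth muscle, above its grey bars.

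Fibroblasts of the formed library were lower in interferon response and antigen presentation genes. Of 16 measured type I interferon response genes 15 were lower, 10 of them at least 2-fold, with a median log2 ratio of -1.06 (random lists -0.32 to 0.25). Bst2, a membrane protein that tethers budding viruses, stood at 575 CPM in the sham and 210.1 CPM in the formed library, 2.74-fold lower (2.53 to 2.96), and Isg15, a ubiquitin-like modifier induced by interferon, was 2.13-fold lower (1.98 to 2.28). MHC class I genes had a median of -0.88, with the class I heavy chain gene H2-D1 1.84-fold lower (1.71 to 1.98). In fibroblast cluster 1, which held 55.6% of the sham and 80.9% of the formed fibroblasts, the interferon median was -0.62. Matrix, modulation and TGF-beta response genes were higher in the class, with medians of 0.52, 0.70 and 0.67. Bgn was 2.41-fold higher (2.34 to 2.48), Mgp 3.18-fold (3.13 to 3.22) and Ltbp2, a protein of elastic microfibrils, 2.99-fold (2.74 to 3.27). The matrix median did not leave the random range in cluster 7 alone (-0.02). Contractile genes were also higher, with a median of 0.68 and Acta2 at 1.97-fold (1.89 to 2.06). Their summed level in T cells was 2535 CPM in the sham and 566 CPM in the formed library, and in monocytes 364 and 530.0 CPM. By the rule of size, Adamtsl2, a secreted protein that binds microfibrils, stood 48.1-fold higher (24.4 to 112) at 210.1 CPM, Cilp, a matrix protein that binds TGF-beta, 49.4-fold higher (13.6 to 409, from 1 cell of the sham library), and Anxa8, an annexin, 25.4-fold higher (12.3 to 63.5). Sfrp2, a secreted Wnt modulator, and Car2, a carbonic anhydrase, were named as lower, on 24 and 6 cells of the sham library.

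Endothelial cells of the formed library held more matrix transcripts and fewer barrier transcripts. Of the 11 measured fibrillar and elastic matrix genes all were higher, 6 at least 2-fold, with a median of 1.18 (random lists -0.31 to 0.38). Eln stood at 1101 and 4415 CPM, 4.01-fold higher (3.77 to 4.27), and Bgn was 3.68-fold higher (3.49 to 3.88). Basement membrane genes had a median of 0.58, with Hspg2, perlecan, 3.35-fold higher (2.86 to 3.95), and 7 of 8 complement genes were at least 2-fold higher, with a median of 1.37. Vasoactive genes had a median of 0.60, with Ace, angiotensin converting enzyme, 2.92-fold higher (2.41 to 3.55), but lay inside the random range in 4 of 12 alternatives, down to 0.30 at a member minimum of 1 count. Barrier and transport genes had a median of -0.94, with 7 of 14 at least 2-fold lower. Itm2a, a membrane protein of brain endothelium, stood at 2115 and 368 CPM, 5.74-fold lower (5.30 to 6.23), whereas the junction genes Cldn5 and Cdh5 were 1.06-fold (1.02 to 1.11) and 1.07-fold (0.973 to 1.17) of the sham level. Endothelial cluster 0, led by Cldn5 and the brain transporter gene Slco1a4, held 34.8% of the sham and 8.37% of the formed endothelial cells, and in cluster 21 alone the barrier median was -0.25, inside the random range, and the matrix median 0.70. Slc16a1, a lactate transporter of the barrier, and Car4, a carbonic anhydrase of capillaries, were named as lower, and Col15a1, Chad and Krt18 as higher. The last 3 rested on 14, 36 and 25 cells of the formed library, and Col15a1 and Krt18 are on the fibroblast and leptomeningeal marker sets. Immediate early genes were lower in endothelial cells as well (median -1.06), with Junb 3.39-fold lower (3.16 to 3.63).

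Macrophages of the formed library were higher in pro-inflammatory genes and lower in reparative ones. The pro-inflammatory list had a median of 0.91 (random lists -0.38 to 0.36), with Ccl5, a chemokine for T cells and monocytes, at 209 and 1126 CPM, 5.39-fold higher (4.77 to 6.10). The reparative list had a median of -0.83 with 5 of 13 genes at least 2-fold lower (-1.88 with no doublets removed), while its member Il10, an anti-inflammatory cytokine, was 2.09-fold higher (1.86 to 2.36). Recruited monocyte genes had a median of 1.16 and NRF2 oxidative stress response genes one of 0.86. The first lay within the random range with no doublets removed (0.30) and the second with each library clustered on its own (0.36). The interferon median of macrophages, 0.80, turned to -0.14 with a minimum of 500 genes per cell. Pdpn, podoplanin, was 6.80-fold higher (4.24 to 11.4), and the eosinophil chemokine gene Ccl24, the growth factor gene Bmp2 and the lectin gene Mgl2 were 6.51-fold, 6.55-fold and 5.09-fold lower. In the mononuclear phagocytes, Ifit1, an interferon-induced antiviral gene, was 5.01-fold higher (4.28 to 5.90), Prdx1, a peroxide-reducing enzyme, was 2.32-fold higher (2.20 to 2.46), and Hpgd, which degrades prostaglandins, 4.90-fold lower. MHC class II genes of that class had a median of -0.58, which became 0.18 when the phagocyte classes were summed together. T cells of the formed library were higher in proliferation genes (median 1.24), with Stmn1, a microtubule regulator of dividing cells, 3.20-fold higher (2.37 to 4.38). Naive T cell genes had a median of -0.68, with the lymph node homing receptor gene Ccr7 3.60-fold lower (2.29 to 5.86), a median that lay within the random range after thinning (-0.30). Immediate early genes were lower in all 3 of these classes, with medians of -0.80 in macrophages, -0.83 in mononuclear phagocytes and -0.74 in T cells.

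The third question was how the ruptured library differed from the sham library. Of 32 lists in its 520 smooth muscle cells 19 lay above and 4 below the random range. The fibrillar and elastic matrix list had a median of 1.70 there (random lists -0.20 to 0.33), with 16 of 19 measured genes at least 2-fold higher. Bgn stood at 3229 CPM, 2.78-fold above the sham library (2.71 to 2.84), and Eln at 1599 CPM, 3.37-fold above it (3.26 to 3.48). The modulation list had a median of 2.55 with 13 of 16 genes at least 2-fold higher, among them Fn1 at 5.44-fold (5.22 to 5.67) and Mgp at 3.68-fold (3.60 to 3.76). That median was 1.47 with the mean of per-cell CPM. Contractile genes again had a median of -0.06, and Acta2 stood at 0.998 times the sham level. TGF-beta response genes had a median of 0.94 (inside the random range in clusters 4 and 5 alone, at 0.03 and 0.13), with Ccn2, a matricellular target of the pathway, 3.50-fold higher (3.32 to 3.68), and basement membrane, protease, protease inhibitor and unfolded protein response genes had medians of 0.69, 1.15, 0.66 and 0.60. Of 18 oxidative phosphorylation genes 17 were lower, with a median of -0.31 and Cox6c, a subunit of cytochrome oxidase, 1.42-fold lower (1.37 to 1.48). Immediate early genes were lower (median -0.62), with Junb 3.03-fold lower (2.94 to 3.12). Smoc2, Gask1b and Dbp were again named by size, at 33.8-fold (23.6 to 49.9), 23.4-fold (16.8 to 33.4) and 18.3-fold (13.8 to 24.6) above the sham library, with Cenpl 6.93-fold and Cebpd 4.998-fold lower.

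Smooth muscle clusters 11 and 17 held 37.7% and 20.2% of the ruptured smooth muscle cells. Clusters 2, 4, 5 and 6 held 90, 59, 49 and 21 of them, so that single clusters fall under the minimum of 100 cells used for classes. In single clusters the matrix median of this comparison ran from -0.38 in cluster 4, where it turned direction, to 0.60 in cluster 2, and the modulation median from 0.04 to 0.83. The modulation median lay inside the random range in clusters 4, 6 and 11, and the matrix median in cluster 6. The vasoactive list had a median of -0.54, while the mean of its members was 0.33. Interferon and MHC class I genes had medians of 1.11 and 0.79. The interferon median turned to -0.01 when members needed 100 counts, and the MHC class I median lay within the random range with the mean of per-cell CPM (0.45). Chemokine genes had a median of 3.16 (1.43 with no doublets removed), at a summed level of 855 CPM against 107471 CPM in neutrophils of the same library. Spp1, osteopontin, a secreted phosphoprotein of macrophages and modulated smooth muscle, stood at 22.8 and 1287 CPM, 56.4-fold higher (50.4 to 63.2), while Spp1 stood at 34863 CPM in fibroblasts, 12357 CPM in monocytes and 119 CPM in T cells of the ruptured library.

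Fibroblasts of the ruptured library, 111 cells, were higher in chemokines. Of 19 measured chemokine and cytokine genes 14 were at least 2-fold higher, with a median of 2.03 (random lists -0.34 to 0.17). Cxcl2, a neutrophil attractant, stood at 233 and 1170.4 CPM, 5.02-fold higher (4.52 to 5.59). Ccl2, a monocyte attractant, stood at 207 and 1063 CPM, 5.14-fold higher (4.59 to 5.76), with 49.3% of its ruptured counts in 3 cells. Cxcl12, which retains leukocytes in bone marrow and vessels, was 2.40-fold lower (2.19 to 2.64). The summed level of the list in fibroblasts was 1932 CPM in the sham, 1630.2 CPM in the formed and 5060.4 CPM in the ruptured library, and in B cells 540.3 CPM in the sham and 972 CPM in the ruptured library. Lists of immune cells were also higher in fibroblasts of the ruptured library, with summed levels of 785 and 3128 CPM for mature activated neutrophil genes and 266 and 857 CPM for pro-inflammatory macrophage genes. Modulation genes had a median of 0.89 (Timp1, an inhibitor of matrix metalloproteinases, 4.58-fold higher, 4.34 to 4.84), TGF-beta response genes one of 0.39 and matrix genes one of 0.33. In cluster 7 alone the chemokine, modulation, TGF-beta and matrix medians lay inside the random ranges (0.10, 0.11, 0.25 and 0.32), and the chemokine median of the class was 1.17 with the automatic doublet threshold. Vasoactive genes had a median of 0.71, inside the random range with the mean of members (0.39). Interferon response genes were lower with a median of -0.61 (-0.42 and inside the random range in cluster 1 alone), and MHC class I genes with one of -0.73 that lay within the random range after thinning (-0.10). Saa3, an acute phase protein gene, and Mmp3, a stromelysin, were named as higher on 8 and 13 cells, with 90.8% and 82.8% of their counts in 3 cells. Ptgds, prostaglandin D synthase of the meninges, stood at 11798 and 72.2 CPM, and Calca, the calcitonin gene-related peptide gene, at 271 and 3.17 CPM.

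Endothelial cells of the ruptured library numbered 91, under the minimum of 100 set for the other classes. Barrier and transport genes had a median of -1.22 (random lists -0.26 to 0.27), with 8 of 14 at least 2-fold lower, Itm2a 7.32-fold lower (6.44 to 8.34) and Cldn5 1.46-fold lower (1.38 to 1.54). The barrier median was -0.58 in cluster 21 alone and -0.51 after thinning. Immediate early genes were lower in the same cells, with a median of -0.87 and 9 of 19 genes at least 2-fold lower. Basement membrane genes had a median of 1.20, with the type IV collagen genes Col4a1 and Col4a2 3.50-fold (2.94 to 4.20) and 3.97-fold (3.26 to 4.86) higher. All 17 measured proliferation genes were higher, 11 at least 2-fold, with a median of 1.11 and Hmgb2, a chromatin protein of dividing cells, 2.09-fold higher (1.70 to 2.59). Chemokine genes had a median of 1.65, with Cxcl2 9.81-fold higher (8.29 to 11.7). Lists of other cell types lay above their random ranges in these cells too, with medians of 0.89 for recruited monocyte, 0.59 for pro-inflammatory macrophage and 0.67 for contractile genes. Ptn, the growth factor pleiotrophin, stood at 1603 CPM in the sham and 106 CPM in the ruptured library, and Car4 was again named as lower. Ccl2, Esm1 and Apln, the last pair being genes of sprouting tip cells, were named as higher on 16, 9 and 9 of the 91 cells, with 81.3%, 81.7% and 71.4% of their counts in 3 cells. Esm1 had no count in sham endothelial cells and was at least 98.5-fold higher at a floor of 3 counts.

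Phagocytes of the ruptured library were lower in MHC class II genes. In the mononuclear phagocytes all 8 measured MHC class II genes were lower, 5 at least 2-fold, with a median of -1.08 (random lists -0.29 to 0.34). Cd74, the invariant chain that guides class II molecules, stood at 33523 and 13819.6 CPM, 2.43-fold lower (2.39 to 2.46), and the class II beta chain gene H2-Eb1 was 2.52-fold lower (2.45 to 2.58). With at most 5% haemoglobin per cell this median was -1.54. In macrophages the median was -1.41, with Cd74 3.71-fold lower (3.49 to 3.94), but -0.09 and inside the random range with a minimum of 500 genes per cell. NRF2 oxidative stress response genes were higher in both classes, with medians of 0.55 in the mononuclear phagocytes and 1.13 in macrophages, where Txn1, thioredoxin, was 2.47-fold higher (2.13 to 2.86). Recruited monocyte genes had a median of 0.85 and genes of activated microglia and foam cells one of 0.56 in the mononuclear phagocytes, and the pro-inflammatory list one of 0.93 in macrophages, where Ccl5 was 7.72-fold higher (6.85 to 8.72) and Lif, a cytokine of the interleukin 6 family, 10.96-fold higher (6.12 to 21.3). Retnla and Cd209f, genes of alternatively activated macrophages, were named as lower. Retnla had no count in 157 ruptured macrophages, at least 64.4-fold lower at a floor of 3 counts, from 9 sham cells, 1 of which held 69.3% of the sham counts. Gbp5, an interferon-induced GTPase, was 7.34-fold higher (4.53 to 12.7) in the mononuclear phagocytes and Cd83, a maturation marker, 3.91-fold lower. Immediate early genes were lower in both classes, with medians of -1.21 and -1.03. T cells were higher in interferon response genes (median 0.96), with Ifi27l2a, an interferon-induced gene, 2.76-fold higher (2.22 to 3.46), and lower in immediate early genes (median -0.70).

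The fourth question was how the ruptured library differed from the formed library, between which the smooth muscle share was 0.303 times as high (0.275 to 0.334) and the neutrophil share 28.4 times as high (21.6 to 38.1). Matrix, contractile and TGF-beta response genes did not stand apart in smooth muscle, with medians of -0.14, -0.01 and -0.10, all inside the random ranges. In single clusters the matrix list lay below its random range in cluster 4 (-0.59) and the TGF-beta list in clusters 2 and 17 (-0.26 and -0.23). In the whole class 13 of 34 lists lay above their random ranges and 1 below. Bgn was 0.725 times the formed level (0.711 to 0.738) and Eln 0.984 times (0.958 to 1.01). Genes named by size were Ccn1, a matricellular relative of Ccn2, 2.15-fold higher (1.99 to 2.32), Snrpf, a spliceosome protein gene, 2.12-fold higher (1.88 to 2.38), Neat1, a long noncoding RNA of nuclear paraspeckles, 2.27-fold lower, and Dkk3, a secreted glycoprotein, 2.01-fold lower. Ttr, transthyretin of the choroid plexus, was 6.20-fold higher, but 91.0% of its counts lay in 3 cells.

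Fibroblasts again stood apart in chemokines between these libraries, with 16 of 23 genes at least 2-fold higher in the ruptured library and a median of 1.56 (random lists -0.25 to 0.14). Ccl2 was 9.97-fold higher (9.18 to 10.8) and Ccl4, a macrophage chemokine, 4.23-fold higher (3.91 to 4.56). Of 111 ruptured fibroblasts 42 held a Ccl2 UMI, and 3 cells held 49.3% of these counts. The median was 0.38 with no doublets removed, and -0.81 in cluster 7 alone, which held 22 ruptured cells. Contractile genes were lower in fibroblasts (17 of 18 genes, median -0.52), at summed levels of 11506 CPM in the formed and 10695 CPM in the ruptured library. Their summed level was also lower in T cells (566 and 295 CPM) and macrophages (1108 and 871 CPM), and other immune classes are not given here. NRF2 genes were higher (median 0.43), with the metallothionein genes Mt1 and Mt2 3.43-fold (3.22 to 3.65) and 3.56-fold (3.18 to 3.99) higher, and matrix genes had a median of -0.02. In endothelial cells the matrix list had a median of -0.91, with Eln 2.48-fold lower (2.35 to 2.62) and Bgn 1.96-fold lower (1.88 to 2.04). Arterial genes had a median of -0.70 and proliferation genes one of 1.24 (0.52 with the mean of per-cell CPM). Ecm1, an extracellular matrix protein gene, was 3.18-fold lower. In monocytes, hypoxia and glycolysis genes had a median of 0.73 (7 of 17 at least 2-fold higher), with the glycolytic enzyme genes Gapdh and Aldoa 1.66-fold (1.59 to 1.75) and 1.67-fold (1.54 to 1.81) higher, and MHC class II genes one of -1.17, with Cd74 2.27-fold lower (2.21 to 2.33). Cxcr4, the receptor of Cxcl12, was 3.25-fold higher (2.82 to 3.74) in the mononuclear phagocytes, where the chaperone gene Dnaja1 was 2.11-fold lower. Rnaset2a and Rnaset2b, near-identical copies whose counts can be split between them, were named as higher there and their values are uncertain. In macrophages the sialyltransferase gene St6gal1 was 4.10-fold higher (2.36 to 7.49), and the MHC class II median was -0.82 (-3.88 with each library clustered on its own). Immediate early genes had medians of -0.66 in macrophages, -0.26 in fibroblasts, -0.21 in mononuclear phagocytes, 0.20 in T cells and 0.30 in monocytes.

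Some of the named genes lie at these places on mouse build GRCm38, all as protein-coding genes. Bgn (ENSMUSG00000031375) spans 73483602 to 73495933 of chromosome X, Itm2a (ENSMUSG00000031239) spans 107397099 to 107403376 of chromosome X, and Eln (ENSMUSG00000029675) spans 134702593 to 134747323 of chromosome 5. Fn1 (ENSMUSG00000026193) spans 71585520 to 71653200 of chromosome 1, Smoc2 (ENSMUSG00000023886) 14279506 to 14404790 of chromosome 17, and Dbp (ENSMUSG00000059824) 45705088 to 45710203 of chromosome 7. Adamtsl2 (ENSMUSG00000036040) spans 27079379 to 27108981 of chromosome 2, Bst2 (ENSMUSG00000046718) 71534255 to 71537456 of chromosome 8, Ccl2 (ENSMUSG00000035385) 82035571 to 82037453 of chromosome 11, and Cd74 (ENSMUSG00000024610) 60803848 to 60812652 of chromosome 18.

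**Figure D3:**
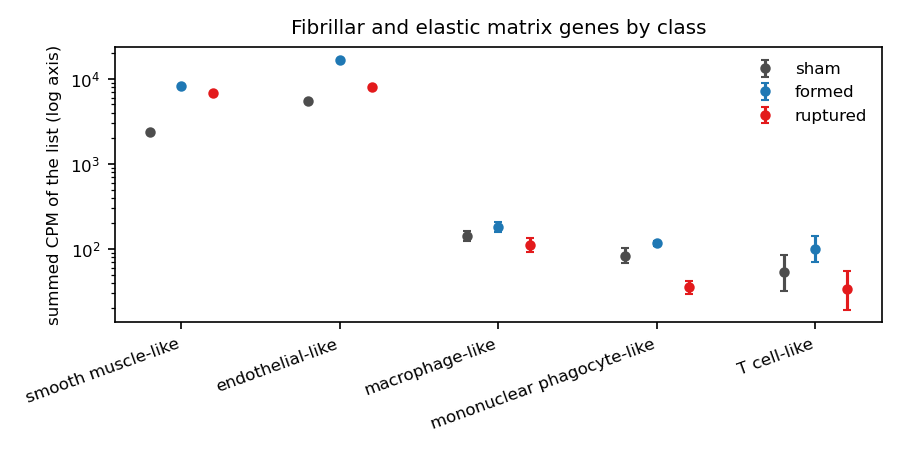
Summed CPM of the fibrillar and elastic matrix list (log axis) by class in the sham, formed and ruptured libraries, with exact Poisson 95% intervals as error bars. Smooth muscle-like cells stand at 2373, 8286 and 6886 CPM, and T cell-like cells at 53.9, 101 and 34.0 CPM.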

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

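The tests of neutrophils against red-cell barcodes, of neutrophils among left-out barcodes and of matrix levels against immune classes were chosen after the result was seen.

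Matrix genes were higher in smooth muscle of both aneurysm libraries, with a median log2 ratio of 1.76 for formed against sham. In formed smooth muscle the summed level of the list was 45.9 times that in macrophages, the highest of the immune classes compared. This argues against free RNA of fibroblasts as far as those immune classes hold it. The 31 oligodendrocyte-like cells of that library stood at 10115 CPM, above smooth muscle itself, so the argument does not hold for every class. Droplets that mix smooth muscle with fibroblasts are argued against by a median of 1.70 without cells holding a UMI of 5 fibroblast markers, and dissociation stress by one of 1.64 within 5 strata of the immediate early level. In smooth muscle clusters 4, 5 and 17 alone the matrix median (0.30, 0.33 and 0.27) lay inside the random range. In no single cluster did the median reach that of the whole class. Clusters 11 and 17 held 1.75% and 1.16% of the sham smooth muscle cells, but 29.7% and 33.0% of the formed ones. A different mix of the clusters may therefore account for much of the pattern, and how much was not tested. The clusters were formed from expression in the same cells. Whether other cells were sampled or the genes were higher within cells stays open. Aneurysm formation and differences between single libraries unrelated to it both stay open, untested, because group and library are the same.

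Neutrophils had a higher share in the ruptured library. More blood of the same makeup is argued against by neutrophils per red-cell barcode, 39.5 times higher in the ruptured than in the sham library. Loss of sham neutrophils to the filters used here is argued against. The sham share would reach 9.29% if every left-out barcode with at most 50% haemoglobin were a neutrophil. Barcodes left out before deposit could not be counted, so loss at that step stays open. Entry of neutrophils into the ruptured wall and an altered makeup of the blood could each give this pattern, and neither was tested.

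Barrier and transport genes were lower in endothelial cells of the formed library, with a median log2 ratio of -0.94. In the larger endothelial cluster alone the median was -0.25, inside the random range of -0.28 to 0.26, so that a different mix of the 2 clusters may account for the pattern. The smaller cluster is led by genes of the list itself, which leaves open whether other cells were sampled or the genes were lower within cells. Dissociation stress is argued against by a median of -0.84 within 3 strata of the immediate early level.

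Some lists were higher in one wall class and lower in another under the same comparison, and these differences were not tested. Interferon response genes had medians of 0.65 in smooth muscle and -1.06 in fibroblasts for formed against sham, and of 1.11 and -0.61 for ruptured against sham. MHC class I genes had medians of 0.75 in smooth muscle and -0.88 in fibroblasts for formed against sham, and of 0.79 and -0.73 for ruptured against sham. Vasoactive genes had medians of -0.73 in smooth muscle, 0.66 in fibroblasts and 0.60 in endothelial cells for formed against sham, and of -0.54 in smooth muscle and 0.71 in fibroblasts for ruptured against sham. With the mean of members in place of the median the last 4 of these lay inside the random range, at 0.38, 0.31, 0.33 and 0.39. In single smooth muscle clusters the interferon and MHC class I medians for formed against sham lay inside the random ranges wherever they were measured.

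Some class shares were on opposite sides of the sham share in the formed and ruptured libraries, which was not tested either. The ratios to sham were 0.761 and 1.42 for T cells, 1.34 and 0.626 for endothelial cells, and 3.06 and 0.728 for fibroblasts, formed first. Barcodes with more than 50% haemoglobin made up 50.4% of the ruptured library against 33.9% of the sham library, and most of them had fewer than 200 genes.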

How the results depend on the processing

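The automatic doublet threshold, the 5% haemoglobin limit, the phagocyte classes summed together, single clusters and lists without class markers were tried after the data were seen. A set of 84 list results outside the random range was chosen after the data were seen, and not all of them are described above. Of these, 65 stayed outside it under every alternative counted for that list, at most 12 each. Single clusters, phagocytes summed and lists without class markers were not counted. Lists were not run under the other mitochondrial limits or the other resolutions, so their dependence on these settings is unknown. The main log2 share ratios (formed against sham, ruptured against sham, ruptured against formed) were -0.53, -2.25 and -1.72 for smooth muscle, 1.42, 6.23 and 4.82 for neutrophils, and 1.04, 1.31 and 0.27 for all phagocytes. Except where a reason is given, the cause of a difference below was not tested. With no doublets removed, the mononuclear phagocyte class gave no values against sham. Thinning gave no value for 8 list results, and a member minimum of 100 counts none for 5. The ruptured library held 91 endothelial cells and 111 fibroblasts.

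With at most 5% mitochondrial UMIs, which removes most smooth muscle cells (median share near 8%), smooth muscle had -2.57 (ruptured against sham) and -1.97 (ruptured against formed), neutrophils 5.52 and 4.05, and all phagocytes 0.45 (formed against sham), 0.089 and -0.37. Endothelial cells had -0.15 for formed against sham and T cells -0.94 for ruptured against sham. With at least 500 genes, which removes neutrophils of low gene number, smooth muscle had -1.96 and -1.40, neutrophils 4.27 (ruptured against formed), and all phagocytes 1.22, 1.80 and 0.58. With each library clustered on its own, neutrophils had 0.59 (formed against sham) and 5.32 (ruptured against sham), and all phagocytes 0.50 (formed against sham) and 0.71 (ruptured against formed).

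The smooth muscle matrix median (formed against sham) was 1.62 with TMM, 1.63 with the mean of per-cell CPM, and 0.60, 0.30, 0.33, 0.55, 0.79 and 0.27 in clusters 2, 4, 5, 6, 11 and 17 alone. For ruptured against sham it was 0.60, -0.38, 0.42, 0.039, 0.39 and 0.30 in these clusters. The modulation median was 0.83, 0.74, 0.37, 0.15, 0.53 and 0.55 for formed against sham and 0.51, 0.085, 0.83, 0.040, 0.12 and 0.79 for ruptured against sham. Medians of some other lists had the opposite sign in single clusters, mostly inside the random range. Immediate early genes were above it in cluster 17 (0.44, formed against sham) and inside it in clusters 11 (0.12, formed against sham) and 5 (0.24, ruptured against sham). Interferon genes were inside it in cluster 2 (-0.21 for formed against sham and -0.34 for ruptured against sham) and below it in cluster 17 (-0.19, ruptured against sham). MHC class I genes were inside it in clusters 6, 11 and 17 (-0.25, -0.019 and -0.56, formed against sham) and 17 (-0.15, ruptured against sham). In smooth muscle for ruptured against sham, the interferon median was -0.014 at a member minimum of 100 counts and the vasoactive mean of members was 0.33.

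In fibroblasts the interferon median was -0.62 in cluster 1 and the matrix median -0.021 in cluster 7 (formed against sham). Their chemokine median for ruptured against formed was 0.38 with no doublets removed, 0.80 with the automatic doublet threshold and -0.81 in cluster 7. The macrophage interferon median for formed against sham was -0.14 with at least 500 genes, -0.058 with no doublets removed and -0.037 with phagocytes summed. The MHC class II median of mononuclear phagocytes was 0.18 with phagocytes summed (formed against sham) and -1.54 with at most 5% haemoglobin (ruptured against sham).

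Among named genes, Ttr in mononuclear phagocytes turned direction. For formed against sham it had -1.66 with at least 500 genes and -0.85 with each library clustered on its own. For ruptured against formed it had 0.24 with each library clustered on its own and 0.67 with no doublets removed. In the main setting 664 of the 667 Ttr counts of formed mononuclear phagocytes lay in 1 cell. In macrophages for ruptured against formed, Areg had -0.24 with each library clustered on its own and -0.0039 with no doublets removed, and Jun 0.22 with each library clustered on its own. Of the other values of 90 named gene results (a gene in a class and comparison) under alternatives, 631 stayed within their intervals and 160 moved in the same direction.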

Other observations

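The phagocyte classes were summed together only after the data were seen, because the libraries spread their phagocytes differently over these classes, and no explanation was tested in this part.

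Summed over macrophages, mononuclear phagocytes, monocytes and microglia (635, 1525 and 1425 cells), recruited monocyte genes had median log2 ratios of 1.18 for formed against sham, 2.29 for ruptured against sham and 1.02 for ruptured against formed. Reparative macrophage genes had medians of -1.72, -1.16 and -0.03. Pro-inflammatory genes had medians of 0.99, 0.29 and -0.56, so that they stood highest in the formed library. Genes of activated microglia and foam cells had medians of 1.41 for ruptured against sham and 0.67 for ruptured against formed, and hypoxia and glycolysis genes 1.17 and 0.82. MHC class II genes had medians of -0.88 for ruptured against sham and -1.03 for ruptured against formed. Immediate early genes, which also mark stress of dissociation, had medians of -1.10 for formed against sham and -1.45 for ruptured against sham, and contractile genes -2.03 and -3.01. These sums mix the makeup of the phagocytes with expression within them. Of the 18 contractile genes, 10 are markers of smooth muscle, so their values may also hold RNA of that class, which was not tested.

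Xist, the transcript of the inactive X chromosome, had 1, 3 and 1 UMIs in the sham, formed and ruptured libraries, and Ddx3y, on the Y chromosome, stood at 143, 112 and 92.0 CPM. Neutrophils per B cell numbered 0.152, 3.86 and 13.3. Contractile genes had a summed level of 2535, 566 and 295 CPM in T cells of the sham, formed and ruptured libraries, and of 648 and 1966 CPM in B cells of the sham and ruptured libraries.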
